A study of Mus musculus with 5 samples.

How the data were processed

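Total RNA from CD4+ T cell samples was sequenced as stranded, ribosomal RNA-depleted libraries with paired reads of 75 bp, per the labels' protocols; how the cells were isolated is not given in the sources used here. The 5 libraries fall into spleen (n = 3) and tumor (n = 2) by the tissue given in the labels. Nothing in the labels says whether replicates came from separate mice, so p-values measure the spread between these samples, which may be technical. Replicate numbers 2 and 3 occur in both tissues without a statement that they mark the same mouse, and they were not used to pair samples.

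Each deposited file lists 1 value per gene symbol for 1 library. The unit is taken as TPM: the deposited values are not whole numbers and sum in each library to less than the total to which TPM are scaled. As a further check, low values of genes with a single annotated transcript were multiplied by transcript length and searched for a step of which they are whole multiples, within 0.05 of a step. The best of 1000 steps was taken, and the range searched was widened once after a first look. In spleen replicate 2 and tumor replicates 2 and 3, 80.6%, 82.8% and 83.6% of values were whole, against at most 21.4% in the same search with shuffled lengths. In spleen replicates 1 and 3 the shares were 23.5% and 32.8%, against at most 17.5% and 19.1%, so there the unit rests on the shared format and the sums. The submitters' processing notes name kallisto, DESeq2 and the mouse build mm10, without versions or the role of each. Where it is clear, such a step is about the worth of 1 read, but it rests on an assumed effective length and on genes with 1 transcript. With no clear step in the other libraries, counts were not derived and precision from counting is not stated. Listed values make up 26.9% to 59.6% of that total per library, and 1 gene, Lars2, takes 9.81% to 25.2% of the listed total. No mitochondrially encoded gene is listed. Because TPM are shares of a total, a rise of abundant transcripts lowers all others, and a different unlisted share per tissue shifts all listed genes together. Of the 19726 symbols 19703 were found in the GENCODE annotation used for coordinates (GRCm38), 14 of the other 23 being in a date form that spreadsheets produce.

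The planned test was one for counts and was not used on TPM. The test set for this case before the data were examined was used: log2(TPM + 1), genes with a mean of at least 1 TPM (12979 genes), and limma 3.58.1 in R 4.3.3 with tissue as the only term, a mean-variance trend, two-sided tests and Benjamini-Hochberg adjustment, with calls at an adjusted p below 0.05. The residual degrees of freedom were 3 and the prior degrees of freedom 44.1, so the error of each gene is mostly that of genes of similar level. Fold changes are on the log2(TPM + 1) scale. The 27 gene lists were fixed before the data were examined: 16 of T cell identity and programmes and 11 of other cell types. They were tested with limma's camera at a preset correlation of 0.01, adjusted within each of the 2 families, and with an estimated correlation and fry as alternatives. Named genes followed a rule fixed beforehand: Cd4, Cd3e and Cd8a; the 6 largest rises and 6 largest falls among called genes with a mean log2(TPM + 1) of at least 3 and no overlap between tissues, leaving out receptor segments, unnamed gene models and markers of other cell types; the called members with the smallest p of each programme list, 2 in the leading direction and 1 in the other; and the marker of each other cell type with the highest mean in each tissue. The levels in that rule, planned on scaled counts, were taken on TPM.

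The test was run on simulated libraries with 200 of 12979 genes changed, under 2 noise models. The changed genes were drawn from those with higher means and moved up and down in equal number. Noise was independent between genes, and no difference in scale between the tissues was simulated. The rates therefore do not cover the lowest tested genes or errors that come from the choice of scaling. They also do not carry over to a changed share as large as the 59.0% of tested genes called in the data. With each gene's own residual SD, 45% of 2-fold and 92% of 4-fold changes were recovered, with 6 false calls among 12779 unchanged genes. With limma's moderated SD, 91% and 100% were recovered, with 7 false calls. The moderated model was adopted while an error in the simulation was being traced, and the residual model was added back so that both are given.

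Alternatives were other scalings (median ratios, equal totals, upper quartile, the top 20 genes left out of the totals), filters, pseudocounts of 0.1 and 10, a stricter threshold of 0.01, a test against a 2-fold change, the replicate number as a block, and each library left out, where a lone tumor library is assumed to vary like the spleen libraries. Scaling on the T cell identity genes was added after seeing the data. Count-based alternatives planned beforehand were not run, since the values are not counts. Python 3.11.15 with matplotlib 3.10.9 drew the figures.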

Results

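RNA was profiled in CD4+ T cell samples taken from the spleen and from MC38 tumors of wild-type C57/Bl6j mice aged 7 weeks. MC38 is a transplantable mouse colon carcinoma line, and CD4+ T cells are the helper and regulatory lymphocytes that carry the CD4 co-receptor. There were 3 libraries from spleen (replicates 1, 2 and 3) and 2 from tumor (replicates 2 and 3). Each library listed 19726 gene symbols as TPM, a relative transcript abundance corrected for transcript length. Read depth was not recovered for all libraries and no counting interval is given. The listed values summed to 268987, 359532 and 292344 TPM in spleen replicates 1, 2 and 3. They summed to 596116 and 569309 TPM in tumor replicates 2 and 3. The remainder of each library's TPM lay in features that were not listed. Across the 12979 genes tested, Pearson's r of log2(TPM + 1) was 0.970 to 0.987 between spleen libraries, 0.988 between the tumor libraries and 0.652 to 0.688 between a spleen and a tumor library. These correlations are across genes, which are not independent replicates. Olfactory receptor genes, 1134 of them and not known to be active in T cells, gave a background level. Their 95th percentile was 10.6 to 16.2 TPM in spleen and 7.59 to 10.7 TPM in tumor libraries.

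The study compared tumor with spleen to ask how the tumor environment alters gene expression in CD4+ T cells. The libraries compared are those labelled as such cells. Genes of macrophages, interferon response, stress response and glycolysis were higher in the tumor libraries, and genes of T cell identity and of naive T cells were lower. In limma's test at an adjusted p below 0.05, 5309 genes rose and 2347 fell in tumor, 69.3% of the calls being rises. Of these, 3420 rose and 669 fell by at least 2-fold, and 427 rose and 3 fell by at least 16-fold, on the log2(TPM + 1) scale, which understates the change of low genes. The tumor and spleen libraries did not overlap for 70.4% of tested genes, against 20% by chance. The balance of rises and falls moved with the scaling: rises made up 52.4% of calls after scaling by median ratios, 32.6% on the upper quartile and 29.0% with equal totals. They made up 26.5% with the top 20 genes left out of the totals and 99.0% after scaling on T cell identity genes. Without tumor replicate 2 the falls numbered 1209, with 4756 rises.

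**Figure D1:**
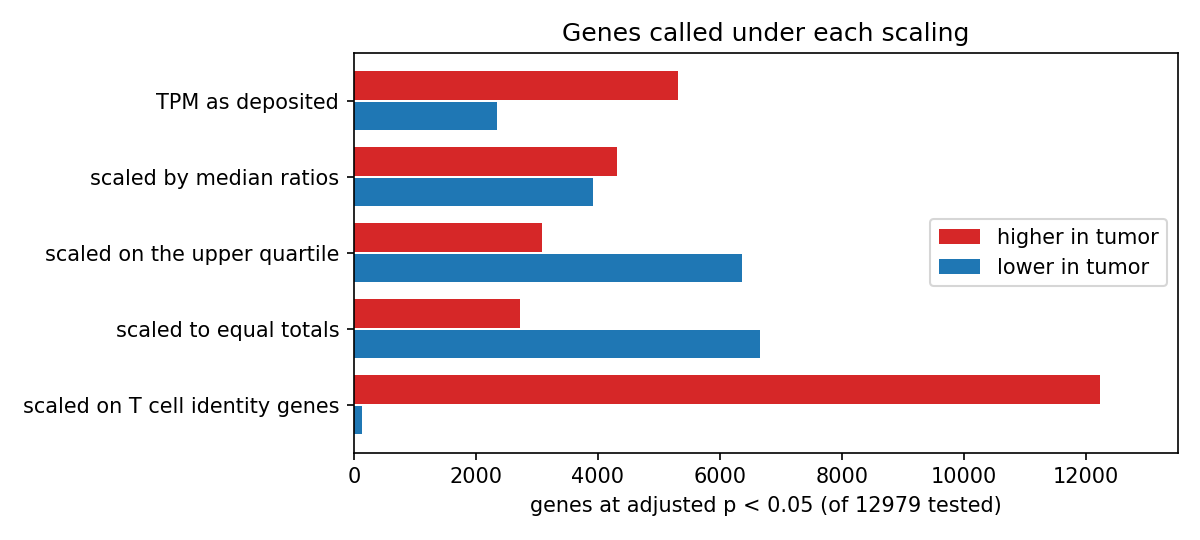
Number of genes called higher (red) and lower (blue) in tumor than in spleen at an adjusted p below 0.05 (limma; 3 spleen and 2 tumor libraries) for the deposited TPM and for 4 scalings. The bars run from 5309 higher and 2347 lower as deposited to 2724 and 6662 with equal totals, and to 12234 and 128 when scaled on T cell identity genes.

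T cell identity genes were lower and macrophage genes far higher in the tumor libraries. All 11 listed genes of T cell identity fell, also when adjusted over the list alone, with a median log2 change of -2.04 (range -3.02 to -1.02; camera adjusted p = 2.9e-10, and adjusted p = 0.256 with an estimated correlation). Scaled on these same genes their median is 0.01 by construction. It stayed negative under each other scaling. Cd4 itself (chromosome 6, 124864692 to 124888221, GRCm38), the co-receptor used to define these cells, stood at 115 ± 16.5 TPM (SD, n = 3) in spleen and 27.0 ± 0.22 TPM (SD, n = 2) in tumor, a log2 change of -2.04 ± 0.21 (SE; limma adjusted p = 5.2e-12). Cd3e (chromosome 9, 44998740 to 45009627), a chain of the T cell receptor complex, went from 86.1 ± 24.4 to 13.3 ± 0.65 TPM (log2 change -2.57 ± 0.22, limma adjusted p = 1.2e-14). Cd8a, which marks CD8 T cells, was at 3.20 ± 0.67 and 3.19 ± 0.08 TPM, within the background level, and its sign changed with the scaling. All 16 genes of the macrophage and monocyte list rose, adjusted over all genes and adjusted over the list alone, with a median log2 change of 7.15 (range 5.35 to 8.69; camera adjusted p = 2.1e-20, and adjusted p = 0.0996 with an estimated correlation). They rose under every scaling. Their summed level was 20.9 ± 0.76 TPM in spleen and 5830 ± 155 TPM in tumor, 279-fold higher. Lyz2 (chromosome 10, 117277331 to 117282321), the lysozyme of myeloid cells, went from 2.73 ± 2.21 to 1233 ± 37.1 TPM, and Ms4a7 from 5.09 ± 1.59 to 299 ± 48.6 TPM.

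**Figure D2:**
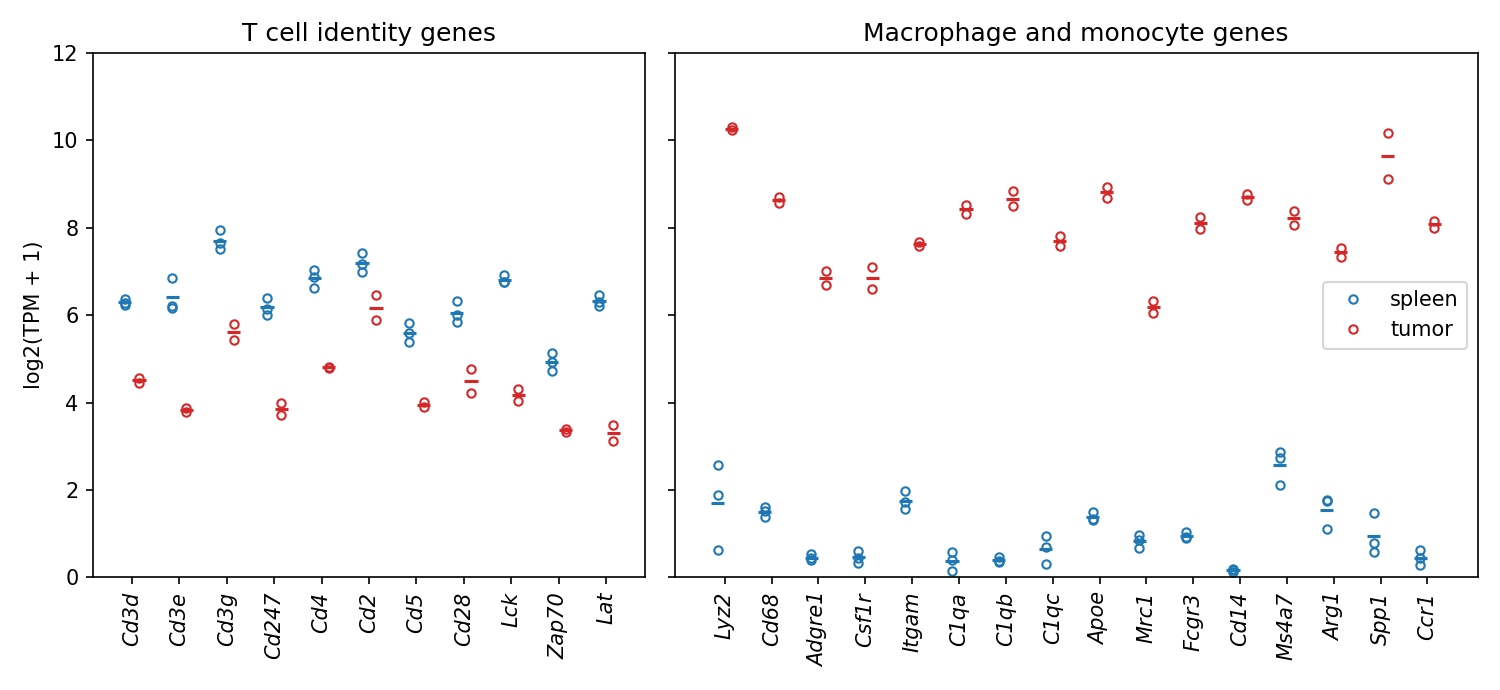
Level of each T cell identity gene (left) and each macrophage and monocyte gene (right) as log2(TPM + 1); circles are single libraries, blue for 3 spleen and red for 2 tumor libraries, and short lines are group means. All 11 T cell genes lie lower and all 16 macrophage genes lie higher in both tumor libraries than in the spleen libraries.

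By the rule for named genes, the largest rises outside the marker lists were those of Il1b, Slfn4, Ccl2, Ccl7, Thbs1 and Lilr4b, and the largest falls those of Tcf7, Als2cl, Lef1, S1pr1, Satb1 and Nsg2. Il1b (chromosome 2, 129364570 to 129371139), which encodes the inflammatory cytokine interleukin-1 beta, went from 0.64 ± 0.40 to 2926 ± 536 TPM (log2 change 10.83 ± 0.22, limma adjusted p = 2.7e-38). The chemokine genes Ccl2 and Ccl7, neighbours on chromosome 11, reached 1209 ± 302.5 and 1058 ± 248 TPM from below 1 TPM in spleen. Slfn4 and Thbs1, the gene of thrombospondin 1, reached 2283 ± 247 and 1324 ± 113 TPM. Lilr4b reached 1897 ± 108 TPM, a value that is uncertain because this receptor gene has a near-identical paralog. Tcf7 (chromosome 11, 52252371 to 52283014), which encodes the T cell transcription factor TCF-1, fell from 114 ± 36.9 to 2.92 ± 0.17 TPM (log2 change -4.83 ± 0.22, limma adjusted p = 1.1e-24). Lef1, a related transcription factor gene, fell from 94.8 ± 28.4 to 4.57 ± 0.07 TPM, and S1pr1, the receptor by which lymphocytes leave lymphoid organs, from 69.2 ± 13.7 to 3.48 ± 0.82 TPM. Satb1, a chromatin organiser, fell from 206 ± 70.7 to 12.5 ± 2.54 TPM, Als2cl by 4.15 and Nsg2 by 3.87 on the log2 scale. Each of these 12 genes was called in the same direction under every setting in which it was tested. Il1b and Slfn4 were not tested with the top 20 genes left out, being among them. The macrophage marker sum was 5830 TPM in the same tumor libraries.

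In the deposited TPM most genes of naive and quiescent T cells were lower in tumor, and more genes of regulatory T cells and of checkpoint receptors rose than fell. Of 18 naive and quiescent genes 14 fell, 1 rose and 3 were not called, with a median log2 change of -1.84 (camera adjusted p = 1.1e-10, and adjusted p = 0.292 with an estimated correlation). When scaled on T cell identity genes 8 rose and 7 fell, with a median of 0.06. The exception was Il7r, the interleukin-7 receptor gene, at 107 ± 34.9 TPM in spleen and 202 ± 27.7 TPM in tumor. Its call was lost with equal totals and on the upper quartile. Of 18 regulatory T cell genes 12 rose, 2 fell and 4 were not called (median 1.08, camera adjusted p = 0.0343, and adjusted p = 0.588 with an estimated correlation). The call was lost without tumor replicate 2 (adjusted p = 0.149) and when scaled on T cell identity genes (adjusted p = 0.233). With equal totals 8 rose and 6 fell, on the upper quartile 9 and 5, and with the top 20 genes left out of the totals 8 and 7. Scaled on T cell identity genes, 16 of the 18 rose and 1 fell. Under that scaling 99.0% of all calls were rises, and camera compares a list with the other genes. Il10, an anti-inflammatory cytokine gene, went from 0.73 ± 0.17 to 58.8 ± 14.9 TPM and Capg, an actin-capping protein gene, from 20.1 ± 3.42 to 385 ± 10.2 TPM. Myeloid cells express both as well. Izumo1r fell from 42.5 ± 6.13 to 4.80 ± 1.81 TPM. Foxp3 (chromosome X, 7573644 to 7595245), the defining transcription factor of regulatory T cells and named here after its values were seen, was at 9.79 ± 1.93 and 11.6 ± 0.90 TPM and was not called (log2 change 0.23 ± 0.21, limma adjusted p = 0.344). It lay below the 95th percentile of the olfactory receptor genes of the same library in spleen replicates 1 and 3, and above it in the other 3 libraries. Of 18 checkpoint and exhaustion genes 12 rose, 4 fell and 2 were not called (median 1.39, camera adjusted p = 0.0244, and adjusted p = 0.256 with an estimated correlation). The call was lost without spleen replicate 2 (adjusted p = 0.0969) and when scaled on T cell identity genes (adjusted p = 0.463). Under that scaling 15 of the list's genes rose and 1 fell. With equal totals 9 rose and 6 fell, and on the upper quartile 10 and 6. Only 2 of its genes fell without spleen replicate 1, spleen replicate 3 or tumor replicate 2. Havcr2, the gene of the TIM-3 receptor that T cells and myeloid cells share, went from 0.40 ± 0.10 to 102 ± 10.5 TPM, Nr4a1 from 7.58 ± 1.46 to 136 ± 2.77 TPM. The inhibitory receptor gene Btla fell from 44.9 ± 8.01 to 3.14 ± 0.31 TPM. For these 3 lists the counts adjusted over the list alone were the same. The macrophage marker sum was 5830 TPM in the same tumor libraries against 20.9 TPM in spleen.

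Effector, helper and activation genes moved in both directions. T cell activation and T cell receptor response genes rose in 13 of 18 cases and fell in 3 (median 2.11, camera adjusted p = 0.0042, and adjusted p = 0.300 with an estimated correlation). The call was also lost when scaled on T cell identity genes (adjusted p = 0.203). There 16 of the 18 genes rose and 1 fell, with a median of 3.70, while the median of all genes was 2.03. The transcription factor genes Nfil3 and Bhlhe40 reached 108 ± 10.8 and 116 ± 1.70 TPM from 0.97 ± 0.22 and 4.58 ± 0.53 TPM. Cd40lg, the CD40 ligand gene by which helper T cells activate other cells, fell from 21.02 ± 3.50 to 0.56 ± 0.43 TPM. Among Th1 and cytotoxic effector genes 10 rose, 6 fell and 2 were not called, and the list was not called as a whole (median 0.62, and -0.24 with equal totals; camera adjusted p = 0.133). It was called on leaving out spleen replicate 1 or 3 or either tumor replicate. Without tumor replicate 3, 9 of its genes rose and 2 fell. Its largest rises were the chemokine genes Ccl4 and Ccl3, at 395 ± 43.7 and 256 ± 69.3 TPM in tumor from 0.86 ± 0.39 and 0.93 ± 0.31 TPM, both also made by macrophages. Ifng, the interferon gamma gene, was at 4.64 ± 0.29 TPM in spleen and 1.86 ± 1.46 TPM in tumor, within the background level. Its fall was no longer called without tumor replicate 3 (limma adjusted p = 0.101). Of the 10 tested Th2, Th17 and Tfh genes 7 fell and 3 rose (median -1.03, camera adjusted p = 0.0244, and adjusted p = 0.256 with an estimated correlation). The median was -0.46 over all 16 members with no filter on low values, and 0.66 when scaled on T cell identity genes. This call was also lost with equal totals and by median ratios, and without spleen replicate 3 (adjusted p = 0.0686) or tumor replicate 3 (adjusted p = 0.078). Cxcr5, the homing receptor gene of follicular helper cells, fell from 9.63 ± 1.501 to 0.99 ± 0.10 TPM, Pou2af1 from 4.07 ± 0.59 to 0.52 ± 0.19 TPM. Both genes lay within the background level in every library. Bcl6, a transcription factor gene of follicular helper cells, rose from 4.52 ± 0.41 to 45.1 ± 7.40 TPM. Tissue residency and migration genes rose in 11 of 19 cases and fell in 5, without a call for the list (median 0.71, and -0.03 with equal totals, where 8 rose and 8 fell; camera adjusted p = 0.0841). It was called on leaving out spleen replicate 1 or 3 or either tumor replicate. Rgs1 and Rgs2, regulators of G protein signalling, reached 2092 ± 131 and 314 ± 36.8 TPM from 19.3 ± 2.03 and 8.60 ± 2.52 TPM. S1pr4 fell from 13.9 ± 1.10 to 1.77 ± 0.77 TPM, near the background level in spleen. Counts adjusted over the list alone were the same for these 4 lists, and in the same tumor libraries the macrophage marker sum was 5830 TPM.

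Interferon and stress genes were higher in tumor nearly throughout. All 22 type I interferon response genes rose (median 4.34, camera adjusted p = 4.8e-16, and adjusted p = 0.256 with an estimated correlation). They rose under every scaling, with 21 of them tested when the top 20 genes were left out of the totals. Rsad2, which encodes the antiviral protein viperin, went from 2.57 ± 0.86 to 614 ± 55.5 TPM and Mx1 from 9.01 ± 2.35 to 476 ± 84.0 TPM. Of 21 immediate early and heat shock genes 20 rose and none fell (median 3.66, camera adjusted p = 4.2e-11, and adjusted p = 0.256 with an estimated correlation). By median ratios 18 of them rose. With equal totals, on the upper quartile and with the top 20 genes left out of the totals 15 rose, and none fell. Atf3, a stress-induced transcription factor gene, went from 0.16 ± 0.09 to 475 ± 32.1 TPM and Ier3 from 0.30 ± 0.19 to 279 ± 41.4 TPM. Genes of endoplasmic reticulum stress and amino acid response rose in 15 of 17 cases, or 16 adjusted over the list alone (median 2.21, camera adjusted p = 4.5e-05, and adjusted p = 0.256 with an estimated correlation). With equal totals 14 rose and 1 fell. Atf4, the transcription factor gene of this response, went from 25.0 ± 2.39 to 211 ± 4.33 TPM and Hspa5, the chaperone gene of the endoplasmic reticulum, from 85.6 ± 11.5 to 647 ± 238 TPM. The counts of the first 2 of these lists did not differ when adjusted over the list alone. The macrophage marker sum was 5830 TPM in the same tumor libraries.

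Most glycolysis and hypoxia genes were higher in tumor, and the other metabolic lists and the cell cycle list had lower medians. The difference between lists was not tested. The largest log2 change was 2.11 among oxidative phosphorylation genes and 1.67 among cell cycle genes. It was 5.61 among cholesterol and fatty acid genes and 6.49 among glycolysis and hypoxia genes. Of 24 glycolysis and hypoxia genes 21 rose, 2 fell and 1 was not called (median 2.39, camera adjusted p = 3.7e-08, and adjusted p = 0.256 with an estimated correlation). Vegfa, the vascular endothelial growth factor gene, went from 1.35 ± 0.39 to 208 ± 12.3 TPM and Slc16a3, a lactate exporter gene, from 1.08 ± 0.24 to 109 ± 8.16 TPM. The glucose transporter gene Slc2a3 fell from 12.8 ± 2.11 to 4.22 ± 0.003 TPM, near the background level in spleen. Of 22 oxidative phosphorylation genes 16 rose and none fell (median 1.05, camera adjusted p = 0.0244, and adjusted p = 0.675 with an estimated correlation). With equal totals, 9 rose and 7 fell. This call was also lost without spleen replicate 1 or 3 and without either tumor replicate, at adjusted p from 0.0628 to 0.283. Cycs, the cytochrome c gene, went from 12.7 ± 0.94 to 58.2 ± 2.82 TPM and Cox5b from 50.5 ± 10.9 to 189 ± 7.46 TPM. Of 23 cell cycle genes 13 rose and 2 fell, with no call for the list (median 0.67, camera adjusted p = 0.443), and 3 rose and 8 fell with equal totals. Falls numbered 0 without tumor replicate 2, where 9 genes rose, and 1 without spleen replicate 3 or tumor replicate 3. Pcna, the replication clamp gene, went from 48.3 ± 5.81 to 156 ± 19.3 TPM. Mcm7, part of the replicative helicase, was at 18.6 ± 1.51 and 11.7 ± 0.85 TPM, and its fall was no longer called without spleen replicate 3 or either tumor replicate. Of 19 cholesterol and fatty acid genes 7 rose and 2 fell, with no call for the list (median 0.21, camera adjusted p = 0.734) and a negative median of -0.10 by median ratios and -0.66 with equal totals. By median ratios 6 rose and 7 fell, with equal totals 5 and 11, on the upper quartile 5 and 10, and with the top 20 genes left out of the totals 5 and 13. Falls numbered 5 without spleen replicate 2 and 1 without tumor replicate 2. Fabp5, a fatty acid binding protein gene, went from 3.44 ± 0.27 to 216 ± 2.69 TPM, Abca1 from 2.66 ± 1.57 to 61.9 ± 4.39 TPM. Fasn, fatty acid synthase, fell from 9.17 ± 1.05 to 3.38 ± 0.64 TPM, within the background level in every library. The counts were the same adjusted over the list alone, and the macrophage marker sum was 5830 TPM in the same tumor libraries.

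**Figure D3:**
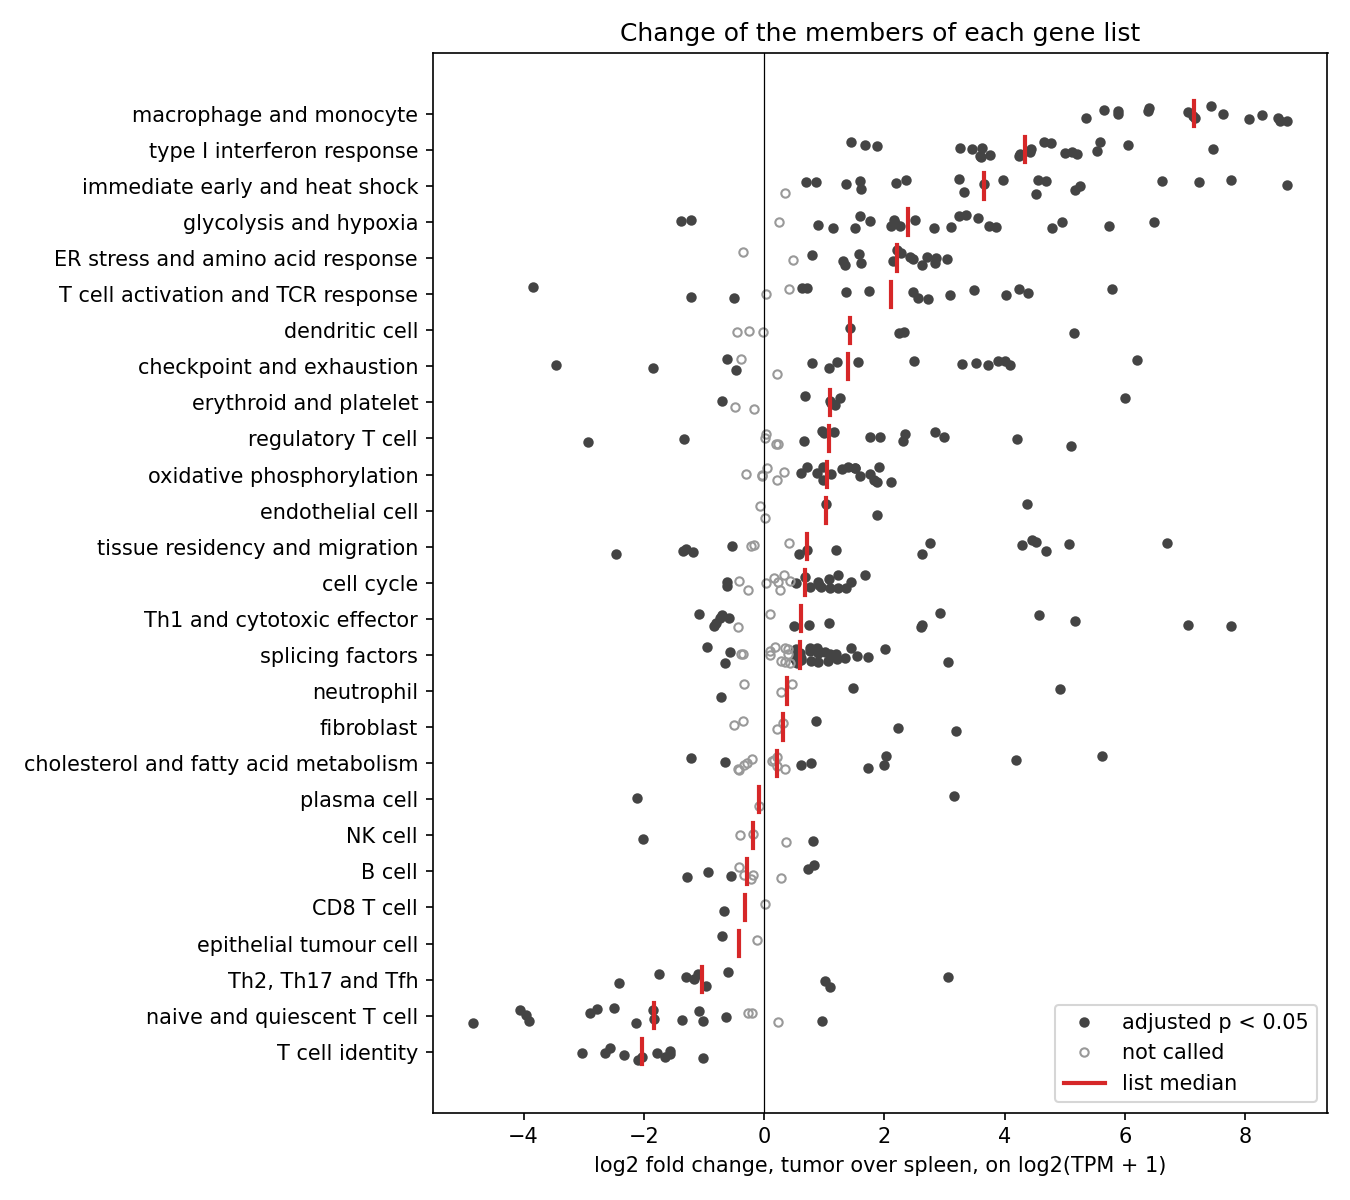
Log2 fold change, tumor over spleen, of each tested member of the 27 gene lists (points; filled where the adjusted p is below 0.05) with the list median in red, on log2(TPM + 1) of the deposited values. The macrophage and monocyte list has the highest median, 7.15, and T cell identity the lowest, -2.04; medians shift together under other scalings.

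Splicing factor genes, which bear on the study's interest in alternative splicing, had no direction that held across scalings. As deposited 26 of 40 rose, 3 fell and 11 were not called, also when adjusted over the list alone, and the list was not called (median 0.60, camera adjusted p = 0.166). It was called without spleen replicate 2 (adjusted p = 0.0181), when scaled on T cell identity genes (adjusted p = 0.00227) and by fry (adjusted p = 0.0242). Without spleen replicate 3 or tumor replicate 2, 18 genes rose, and without tumor replicate 3, 16 rose and 2 fell. None fell without tumor replicate 2. By median ratios 18 rose and 5 fell, on the upper quartile 9 and 15, and with equal totals 7 and 20. All 40 rose when scaled on T cell identity genes. Mbnl2, which encodes a muscleblind splicing regulator, went from 19.5 ± 3.70 to 168 ± 4.04 TPM and Qk, which encodes the RNA-binding protein quaking, from 13.2 ± 1.42 to 55.7 ± 3.92 TPM. Both rose under every scaling. Srpk1, the gene of a kinase of splicing factors, went from 216 ± 10.7 to 113 ± 27.3 TPM, a fall no longer called without tumor replicate 2 (limma adjusted p = 0.0624). The macrophage marker sum was 5830 TPM in the same tumor libraries. Splicing itself was not analysed here.

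Markers of other cell types stayed low beside those of macrophages. Of the 11 lists the macrophage list alone was called by camera with the preset correlation, none with an estimated correlation, and 9 by fry, which does not compare a list with other genes. Dendritic cell markers summed to 15.8 ± 3.59 TPM in spleen and 142 ± 37.1 TPM in tumor, mostly Itgax at 112 ± 33.9 TPM, a gene that macrophages share. Neutrophil markers summed to 22.5 ± 2.50 and 73.2 ± 4.46 TPM, mostly Csf3r in tumor at 55.5 ± 3.28 TPM. Of the 6 tested neutrophil markers 2 rose and 1 fell. The fall was that of Cxcr2, from 15.5 ± 2.88 to 9.19 ± 3.49 TPM, near the background level. Erythroid and platelet markers summed to 15.97 ± 2.05 and 121 ± 21.7 TPM, of which Pf4, the platelet factor 4 gene, gave 94.5 ± 18.03 TPM in tumor. Of the 9 tested markers 6 rose, 1 fell and 2 were not called, and 1 rose in the test against a 2-fold change. Itga2b, from the same list, was not called, at 2.90 ± 0.50 and 2.52 ± 0.82 TPM. Fibroblast markers summed to 22.7 ± 5.62 and 58.4 ± 8.45 TPM, with Fn1 at 27.9 ± 10.1 TPM in tumor. Of the 7 tested fibroblast markers 3 rose and none fell. Col1a2 was not called, at 7.74 ± 2.33 and 5.24 ± 2.21 TPM. Endothelial markers summed to 73.0 ± 4.29 and 115 ± 8.49 TPM, with Pecam1 at 62.0 ± 6.47 and 59.0 ± 5.92 TPM. Sums in spleen and tumor were 38.6 ± 2.32 and 31.6 ± 3.32 TPM for B cells, and 31.3 ± 6.41 and 21.9 ± 1.60 TPM for plasma cells. They were 14.5 ± 1.14 and 9.92 ± 0.05 TPM for NK cells, 6.95 ± 0.46 and 5.20 ± 0.40 TPM for CD8 T cells and 10.6 ± 2.35 and 7.30 ± 0.25 TPM for epithelial tumor cells. Jchain, the joining chain gene of antibodies, made up most of the plasma cell sum in spleen, at 28.2 ± 6.37 TPM. With 3 libraries against 2, no exact permutation test of a single value can give a p below 0.1, so the calls rest on the spread that limma shares across genes.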

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

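Scaling on T cell identity genes was chosen after seeing the data; all other settings were planned, with scalings planned for counts carried over to TPM. The planned count-based tests were not run, because the values are not counts. Of the 74 named genes, 52 kept their direction and call under all settings that tested them and 60 under every left-out library. The median log2 change of all genes shifted by -0.28 by median ratios, -0.68 on the upper quartile, -0.77 with equal totals, -0.84 with the top 20 genes left out of the totals and 1.80 on T cell identity genes. Depth was not recovered for all libraries, and genes within the background level carry little weight in either direction.

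For tumor against spleen, genes called were 7656 and genes higher in tumor and genes lower in tumor 5309 and 2347. Higher and lower genes numbered 4313 and 3920 by median ratios, 2724 and 6662 with equal totals, 3078 and 6366 on the upper quartile, 2639 and 7312 with the top 20 genes left out of the totals, and 12234 and 128 (12362 in all) on T cell identity genes. An adjusted p below 0.01 left 4680 and 1552, and the test against a 2-fold change left 2199 and 274 (2473 in all); both are stricter by construction. With libraries left out in turn, lower genes ranged from 1209 to 2623, higher genes from 4390 to 5842 and all calls from 5965 to 8465; the cause was not tested. Filters and pseudocounts moved no count by over 1.5 times. The macrophage and monocyte marker sum, log2 tumor over spleen, was 8.13, and 7.18 with equal totals, lower because the tumor totals are 1.90 times higher. Gene list tests called 11 of 16 lists, 0 with an estimated correlation and 16 by fry, which does not compare a list with other genes. Other cell type lists gave 1 of 11, 0 with an estimated correlation, 9 by fry and 2 on T cell identity genes. The estimated correlation between a list's genes was taken from these data, which leave 3 residual degrees of freedom. The cause of the differences between settings was not tested.

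Cd8a turned negative by median ratios (-0.24), on the upper quartile (-0.61), with equal totals (-0.69) and with the top 20 genes left out (-0.75), where Il7r was at -0.053. On T cell identity genes these turned positive: Cd4 0.011, Ifng 0.41, Mcm7 1.34, Slc2a3 0.45, Srpk1 1.13, Fasn 0.56, Cd8b1 0.89, Ebf1 1.64, Cd22 1.54, Siglech 1.17, Cxcr2 1.20, Klre1 1.30, Itga2b 1.38, Krt7 1.42, Lgals4 0.88, Col1a2 1.31 and Pecam1 1.99. That scaling raises the tumor values relative to spleen, each gene by its own amount on the log2(TPM + 1) scale. With libraries left out, genes near 0 changed sign: Cd8a ranged from -0.070 to 0.14, Ebf1 from -0.58 to 0.14, Itga2b from -0.40 to 0.079, Krt7 from -0.42 to 0.17 and Pecam1 from -0.17 to 0.032. The lists that changed direction had no call on either side. These were list splicing factors (adjusted p = 0.942 with equal totals), list cholesterol and fatty acid metabolism (0.929 by median ratios and 0.942 with equal totals), list plasma cell (0.869 with equal totals and 0.0903 by fry), list cell cycle (0.741 without tumor replicate 2, in a range of 0.426 to 0.805 over left-out libraries), and on T cell identity genes list neutrophil (0.733), list erythroid and platelet (0.733) and list fibroblast (0.982). The cause was not tested.

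The replicate block, with the number as a term, gave 4877 higher and 2013 lower genes. Number 1 occurs only in spleen, so spleen replicate 1 does not bear on these fold changes. They equal those with that library left out. The labels do not say what samples of the same number share. Their deviations from the group means correlated across genes at 0.202 for number 2 and 0.0661 for number 3. With 2 tumor libraries the tumor deviations are mirror images of each other, so these values cannot tell whether the samples are paired. With the replicate block Krt7 was at 0.018 and list plasma cell turned at an adjusted p of 0.971; the lists of regulatory T cells (0.0744) and oxidative phosphorylation (0.382) were not called, and those of Th1 (0.0107) and residency (0.0187) were.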

Other observations

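The gene families in the next paragraph, and the tests of every explanation except the one on further myeloid genes, were chosen after the results were seen.

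Antigen presentation and chemokine genes formed further large groups of the tumor libraries. Of 9 genes of MHC class II presentation 7 rose, 1 fell and 1 was not called, with a median log2 change of 5.38 (camera adjusted p = 3.5e-05, and adjusted p = 0.281 with an estimated correlation), and their sum went from 31.9 ± 3.43 TPM (SD, n = 3) in spleen to 3120 ± 1538 TPM (SD, n = 2) in tumor. H2-Aa, a class II chain, was at 520 and 1162 TPM in tumor replicates 2 and 3. H2-Ob, which is typical of lymphocytes, fell from 12.7 ± 2.25 to 2.43 ± 0.66 TPM, near the background level in spleen. Of 21 tested chemokine ligand genes 15 rose and none fell (median 4.99, camera adjusted p = 2.1e-11, and adjusted p = 0.0153 with an estimated correlation), their sum going from 49.6 ± 1.75 to 6501 ± 879 TPM; 4 of them fell with equal totals and on the upper quartile, and 5 with the top 20 genes left out of the totals. With no filter on low values 17 of all 35 rose and 1 fell, with a median of 0.54. Of 80 ribosomal protein genes 58 fell and 4 rose (median -0.69, camera adjusted p = 1.3e-11, and adjusted p = 0.346 with an estimated correlation), a fall also found by median ratios, with equal totals and on the upper quartile, and turned into a rise of all 80 when scaled on T cell identity genes. Falls numbered 32 without tumor replicate 2 and 43 without spleen replicate 3, and 0 in the test against a 2-fold change.

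The macrophage and monocyte genes of the tumor libraries, 279-fold higher in sum, stand beside a fall of the T cell identity genes by a median of 2.04 on the log2 scale. A scale factor per library moves all genes alike and is argued against by the gap of 9.19 log2 units between the 2 lists. Myeloid cells in the tumor samples are a candidate explanation: of 20 further myeloid genes chosen before their values were seen, 18 rose, the other 2 not being listed, and abundant members such as Ms4a6d and Tyrobp reached 875 and 787 TPM on average, with no gene of the macrophage list above a mean of 5.09 TPM in spleen. They cannot be told apart from uptake of myeloid transcripts by T cells that keep their own: TPM are shares, so either would dilute the identity genes, which lie at -2.27 log2 units from the median of all genes. How the CD4+ cells were isolated is not given in the sources used here, and a loss of T cell transcripts within T cells of the tumor stays open beside both, so the rises of interferon, stress and glycolysis genes cannot be assigned to a cell type from these libraries.

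Foxp3 and part of the naive T cell genes did not move with the T cell identity genes. Set against the mean of those genes within each library, Foxp3 was 2.34 log2 units higher in tumor than in spleen, Ctla4 4.45, Ccr8 4.89 and Icos 3.89. Gpr83 was at -0.08, Izumo1r at -1.10, Lef1 at -2.25 and Tcf7 at -3.16. The median log2 change of all genes scaled on T cell identity genes was 2.03 on log2(TPM + 1), near the value of Foxp3. Gpr83 stood at -5.36 and -3.86 in tumor replicates 2 and 3, on either side of its spleen mean of -4.53. In spleen, Gpr83 and Ccr8 lay below Foxp3, which is near the background level there. By its median alone, the naive set leaves open a lower T cell share that acts on all T cell genes alike. That median log2 change was -1.84, against -2.04 for the identity genes. The SD between members was 1.63 for the naive genes and 0.58 for the identity genes. Scaled on T cell identity genes, 8 of 18 naive genes rose and 7 fell, against 2 and 3 of the 11 identity genes. The near medians therefore do not show that the naive genes moved together. Of 17 naive genes 4 (Tcf7, Lef1, S1pr1 and Satb1) lie below the lowest identity gene by more than the SE of the difference. Such a lower T cell share does not account for these 4, if the identity genes are taken as those of T cells alone. They are among the largest falls of all genes, and the test was set after they were seen. Foxp3 lies 1.25 log2 units above the highest identity gene, and a lower T cell share is left open for it as well. It is near the background level in spleen. Cd8a, whose low TPM did not change, gave 2.11 on the scale on which Foxp3 gave 2.34. A higher share of regulatory T cells among the T cells of the tumor was not decided either: 16 of the 18 regulatory T cell genes lie above the highest identity gene, but so do 95% of all tested genes, and several of the 18, such as Il10 and Capg, are also myeloid genes.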
